A study of Homo sapiens with 12 samples.

How the data were processed

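Total RNA was extracted from MCF7-derived cell pellets with TRIzol and a miRNeasy column kit, per the labels' protocols, and 12 libraries were sequenced, 3 for each of 4 lines. The library kit, the selection of RNA and the strand setting are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene for all 12 libraries. Per the submitters' processing notes, the tools were FastQC 0.11.8, Bowtie2 2.3.3.1, featureCounts 2.0.1 and edgeR 3.28.1 and the build was GRCh38, with no role or order stated. Bowtie2 does not align reads across introns, and whether reads over exon junctions were counted is not given in the sources used here. Because the strand setting is unknown, reads of overlapping and antisense genes cannot be told apart, and counts of histone, HLA and other near-identical gene families are uncertain. The columns of the 3 ENDX-R, 3 4HT-R, 3 ICI-R and 3 vehicle libraries were matched to samples by the names in the labels.

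The column names of the deposited count table also carry a flow cell lane, which was 3 for vehicle and ENDX-R and 4 for 4HT-R and ICI-R. Lane therefore does not enter ENDX-R against vehicle or 4HT-R against ICI-R and cannot be separated from line in the other 4 contrasts. No lane held more than 1 group of a confounded contrast, so no value within a lane can be given for those.

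The deposited count table had 15456 rows, of which 161 repeated an Entrez gene with identical counts and were dropped, which left 15295 genes, 10 of them at 0 in every library. Of the Entrez identifiers, 15287 were found in the RefSeq table of GRCh38.p14, which supplied symbols and coordinates, and 89 symbols were updated. The counts were tested for a filter that had been applied before deposit. Only 43 genes had fewer than 3 of the 6 vehicle and 4HT-R libraries at 0.25 CPM, against 324 to 727 genes for the other 5 pairs of groups. Genes above 1 CPM in 1 line and below 0.1 CPM in the other 3 numbered 27 for vehicle, 28 for 4HT-R, 0 for ENDX-R and 0 for ICI-R. The table therefore lacks most genes expressed in ENDX-R or ICI-R and silent in both vehicle and 4HT-R.

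Total counts per library were 46112705, 43039222 and 35437695 in vehicle, 37675596, 34053897 and 39305184 in ENDX-R, 41368809, 41313260 and 39872407 in 4HT-R and 37120679, 40351851 and 35925607 in ICI-R. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 6.10 to 38.3), so none was the same library sampled again. Repeat libraries from the same RNA are not excluded by this. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. At a biological coefficient of variation of 10.5%, small differences passed the test.

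Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, which kept 15256 and removed 39, and libraries were scaled by TMM (factors 0.958 to 1.038). One model with a mean for each of the 4 groups, on 8 residual degrees of freedom, was fitted with edgeR's quasi-likelihood functions (glmQLFit and glmQLFTest), and 6 contrasts were tested with BH adjustment at 0.05. Fold changes are from this fit, with a standard error from the fold change and the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. A fold against a group with no counts is a lower bound against 3 counts over the group ("at least"), and for 1 to 3 counts the ratio is given with its 95% counting interval. The same steps run on simulated counts with known changes at the depth of ENDX-R against vehicle recovered 74.6%, 91.0% and 97.0% of genes changed 1.5-, 2- and 4-fold, over 15130 genes, with 64.2%, 91.0% and 95.5% at the depth of 4HT-R and 59.7%, 91.0% and 98.5% (15120 genes) at that of ICI-R. Each simulation changed 200 genes in 1 line and gave 12, 11 and 12 false calls in that order. In the real contrasts 51.5 to 69.1% of genes were called. The simulations therefore do not test the scaling where most genes differ.

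The design, the alternatives, 22 gene lists and the rule for naming genes were fixed before the data were examined. The lists were estrogen-induced and estrogen-repressed genes, luminal epithelial, basal or myoepithelial, mesenchymal, fibroblast and blood or endothelial markers, growth factor signalling, proliferation, G1 regulators, interferon response, antigen presentation, cholesterol synthesis, unfolded protein and stress response, hypoxia and glycolysis, inflammatory NF-kappaB genes, steroid receptors and coregulators, drug metabolism and transport, apoptosis regulators, immediate early genes, mitochondrially encoded genes and histone genes without poly(A) tails. Lists with at least 5 tested members, 21 of them, were tested with limma's camera on log2 CPM at a preset correlation of 0.01, with BH adjustment within a contrast, and again with the correlation estimated for each list and with fry. In the report, a list's adjusted p is from camera, and counts of members higher or lower are from edgeR over all genes. List members outside the table, among them 9 of the NF-kappaB, 9 of the fibroblast and 11 of the drug metabolism list, were not analysed here.

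The naming rule took, for each line against vehicle and for ENDX-R against 4HT-R, 16 fixed genes (ESR1, PGR, GREB1, TFF1, PDZK1, CCND1, GATA3, FOXA1, EGFR, ERBB2, IGF1R, VIM, CDH1, MKI67, BCL2 and ABCB1). It added the 5 called genes with the highest and the 5 with the lowest log2 fold change at an average log2 CPM of at least 3, and up to 4 called members of each list with the greatest change at an average log2 CPM of at least 1. For line-specific genes it took the 5 with the greatest change per line and direction. XIST, Y-linked genes, pseudogenes, antisense genes and clone names were left out. The contrasts of ENDX-R or 4HT-R with ICI-R name genes chosen in this way elsewhere. ABCB1 was not analysed here.

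Similarity of lines was measured by correlation and covariance of log2 differences from vehicle, set beside simulated unchanged lines that share the vehicle libraries. It was also measured by a mean squared log2 difference that does not use vehicle. Replicate numbers are shared between groups in the labels. Deviations from the group means of same-numbered libraries all correlated above 0.1 only between ICI-R and vehicle (0.473, 0.110 and 0.689). Between ENDX-R and 4HT-R the values were 0.704, -0.11 and 0.68. Whether the numbers mark a pairing is not settled by these data, and the main design has no block.

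Alternatives covered other scaling (RLE and upper quartile), other filters, DESeq2 1.42.0, limma voom, fits on the compared groups alone, a replicate block, a threshold of 0.01 and leaving out each library in turn. After seeing the data, 4 more were added: only genes expressed in all vehicle libraries, the leading axis of variation within groups as covariate, leaving out the 4 libraries at 1 end of that axis, and removing the GC trend of each library.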

Results

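RNA sequencing measured gene expression in 4 lines made from MCF7, a human breast cancer cell line that carries estrogen receptor alpha and grows in response to estrogen. Each line had been kept for 24 months in medium with 0.1% ethanol (vehicle) or with 1 µM of an antiestrogen. The antiestrogens were Z-endoxifen (ENDX-R line), 4-hydroxytamoxifen (4HT-R line) and ICI, the usual short name of fulvestrant (ICI-R line). Endoxifen and 4-hydroxytamoxifen are active metabolites of tamoxifen that bind the receptor, and fulvestrant is a receptor antagonist that also lowers the amount of receptor protein. Each line had 3 libraries, 12 in all, and the series asks how a line resistant to endoxifen differs from lines resistant to the other antiestrogens. Total counts per library ran from 35437695 to 46112705 in vehicle, 34053897 to 39305184 in ENDX-R, 39872407 to 41368809 in 4HT-R and 35925607 to 40351851 in ICI-R. Mitochondrial transcripts took 7.39 ± 0.310% of counts in vehicle, 7.46 ± 0.545% in ENDX-R, 6.57 ± 0.149% in 4HT-R and 7.30 ± 0.556% in ICI-R (SD, n = 3 each), and the 10 most abundant genes together took 7.04 to 8.76% per library. Levels are given as counts scaled to a common library size (CPM), mean ± SD over 3 libraries, and coordinates are on GRCh38 from the start to the end of the annotated gene, exons and introns together. All intervals on ratios and all lower bounds given for genes with few counts cover counting error only.

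In each of the 3 resistant lines, most of 37 genes that estrogen is known to induce were lower than in vehicle (30 in ENDX-R, 29 in 4HT-R and 33 in ICI-R by edgeR), and EGFR, the epidermal growth factor receptor, was higher. ESR1, which encodes estrogen receptor alpha (Entrez 2099, chromosome 6, 151690496 to 152103274), stood at 526 ± 19.8 CPM in vehicle, 61.4 ± 2.41 in ENDX-R, 295 ± 8.29 in 4HT-R and 36.3 ± 0.546 in ICI-R (SD, n = 3). GREB1, an estrogen-induced cofactor of the receptor (Entrez 9687, chromosome 2, 11534116 to 11642788), fell from 1497 ± 10.7 CPM to 5.43 ± 0.851, 4.56 ± 0.676 and 5.90 ± 0.172 CPM in the same order. EGFR (Entrez 1956, chromosome 7, 55019032 to 55207338) rose from 8.37 ± 0.699 CPM to 72.8 ± 3.22, 49.7 ± 0.846 and 83.5 ± 1.42 CPM.

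**Figure D1:**
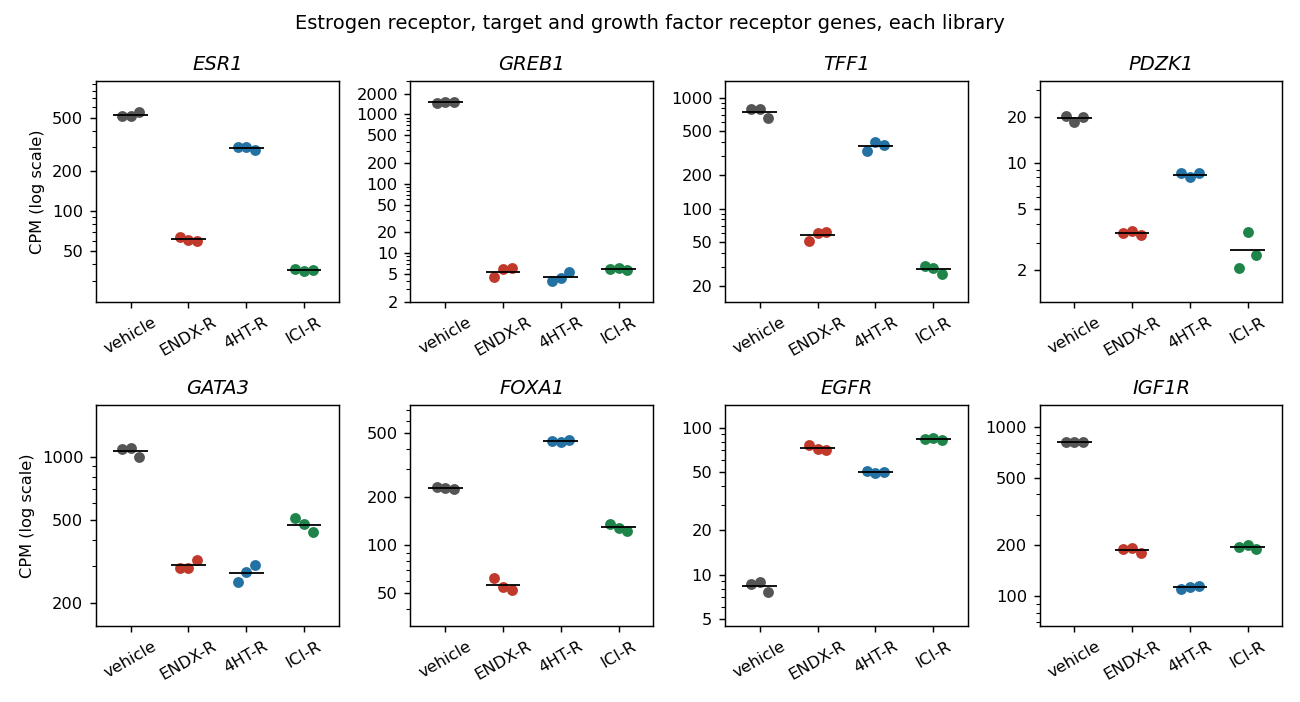
CPM (log axis) of ESR1, GREB1, TFF1, PDZK1, GATA3, FOXA1, EGFR and IGF1R in each library of the vehicle, ENDX-R, 4HT-R and ICI-R lines, 1 point per library and 3 per line, with a bar at the mean of each line. ESR1 lies at 526 CPM in vehicle and at 61.4, 295 and 36.3 CPM in ENDX-R, 4HT-R and ICI-R, and FOXA1 lies above vehicle in 4HT-R and below it in ENDX-R and ICI-R.

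The ENDX-R line, compared with vehicle, had lower levels of most estrogen-induced genes and higher levels of most interferon-response and antigen-presentation genes. ESR1 was 8.56-fold lower (log2 fold change -3.10, SE 0.06) and PGR, the progesterone receptor gene and a classic estrogen target (Entrez 5241, chromosome 11, 101029624 to 101130668), was 2520-fold lower, at 0.0356 ± 0.0309 against 101 ± 7.18 CPM. TFF1, a secreted estrogen-induced peptide (chromosome 21, 42362282 to 42366535), was 13.0-fold lower at 57.6 ± 5.86 against 747 ± 77.4 CPM. BCL2, an inhibitor of apoptosis (chromosome 18, 63123346 to 63319778), was 143-fold lower at 0.127 ± 0.0339 against 18.8 ± 0.957 CPM. EGFR was 8.67-fold higher. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment was 6.43e-15 for ESR1, 1.60e-14 for PGR and 1.18e-13 for EGFR.

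In ENDX-R the highest fold changes included CDH5, which encodes the endothelial adhesion molecule VE-cadherin (chromosome 16, 66366622 to 66404786) and was 3550-fold higher (95% counting interval 637 to 140000). DIO2, which converts thyroxine to the active thyroid hormone (Entrez 1734, chromosome 14, 80197525 to 80231054), was 2376-fold higher at 1245 ± 113 against 0.533 ± 0.171 CPM. ROR1, TDRD1 and TCIM were 2160-fold (597 to 17800), 1630-fold (559 to 7930) and 1390-fold (385 to 11500) higher. GFRA1, a co-receptor for glial cell line-derived neurotrophic factor (Entrez 2674, chromosome 10, 116056925 to 116273614), was 8808-fold lower. SLFN11, which blocks stalled replication forks under DNA damage (chromosome 17, 35350305 to 35373853), had no counts in the 3 ENDX-R libraries and was at least 1320-fold lower. CDKN2B, an inhibitor of CDK4 and CDK6 (chromosome 9, 22002903 to 22009313), also had no counts there and was at least 334-fold lower. CA2, a carbonic anhydrase, was 1363-fold lower.

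Of the lists fixed before the data were examined, 37 estrogen-induced genes had 3 members higher and 30 lower in ENDX-R than in vehicle (camera, BH adjusted p = 3.0e-12), with GFRA1, GREB1, PGR and ELOVL2 (95.9-fold lower) among the latter. Of 30 luminal epithelial genes, 5 were higher and 22 lower (adjusted p = 0.000122), among them AR, the androgen receptor gene (34.4-fold lower), AGR2 (101-fold lower), SCUBE2 (75.0-fold lower) and TFF3 (44.1-fold lower). FOXA1 and GATA3, transcription factors of luminal cells, fell by 2.02 on the log2 scale (SE 0.07) and from 1059 ± 53.1 to 303 ± 16.7 CPM. Of 33 interferon-response genes, 29 rose and 3 fell (adjusted p = 9.37e-10), with SAMD9 171-fold, IFIT3 128-fold, IFIT2 69.7-fold and DDX60 61.9-fold higher. All 13 measured antigen-presentation genes rose (adjusted p = 4.12e-06), including B2M, the light chain of class I molecules, at 487 ± 40.9 against 72.9 ± 5.43 CPM, and the peptide transporter genes TAP1 (6.75-fold) and TAP2 (7.29-fold). Of 23 mesenchymal genes, 12 rose and 5 fell (adjusted p = 0.00977). SERPINE1, an inhibitor of plasminogen activators, rose 226-fold to 133 ± 2.55 CPM, LOXL2 57.0-fold, SNAI2 16-fold and FN1, fibronectin, 15.1-fold. VIM, vimentin, also of this list, fell by 1.16 on the log2 scale (SE 0.16) from 5.34 ± 0.735 to 2.40 ± 0.154 CPM.

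Further lists moved in the ENDX-R line against vehicle by camera with BH adjustment. Of 20 genes of the unfolded protein and stress response, 13 rose and 2 fell (adjusted p = 0.00236), with DDIT4 9.38-fold and HERPUD1 5.85-fold higher. Of 11 inflammatory NF-kappaB genes, 8 rose and 1 fell (adjusted p = 0.00168), with ICAM1 6.56-fold higher and CXCL8, interleukin 8, at least 26.5-fold higher. CXCL8 had only 22, 14 and 33 counts in ENDX-R and 0 in each vehicle library. The deposited table largely lacks genes silent in both vehicle and 4HT-R. Such a member could therefore enter the list mainly by its level in 4HT-R, which favours higher members. Of 19 steroid receptor and coregulator genes, 3 rose and 12 fell (adjusted p = 0.00977), GPER1 by 16.1-fold. Among 13 regulators of the G1 phase, 1 rose and 10 fell (adjusted p = 0.00273), including the inhibitors RBL2 (4.70-fold) and CDKN1B (2.95-fold). Of 17 histone genes whose transcripts lack poly(A) tails, none rose and 16 fell (adjusted p = 1.0e-05), H3C8 by 4.83-fold, although counts of such near-identical genes are uncertain. Of 32 proliferation genes, 3 rose and 19 fell (adjusted p = 0.0115), PLK1 by 2.23-fold and MCM2 by 1.85-fold, and of 13 immediate early genes, 8 rose and 1 fell (adjusted p = 0.0115), FOSL1 by 8.29-fold. The calls of the last 2 lists ended with an estimated correlation (adjusted p = 0.201 and 0.253 with an estimated correlation), and the other 10 held, with adjusted p from 0.000673 to 0.0441 with an estimated correlation.

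No call was made in ENDX-R against vehicle for the other lists tested with camera and BH adjustment. Of 28 growth factor signalling genes, 14 were higher and 10 lower (adjusted p = 0.199), with BTC 25.6-fold and MET, the hepatocyte growth factor receptor gene, 8.92-fold higher and ERBB4 40.4-fold lower. Of 20 drug metabolism and transport genes, 8 were higher and 10 lower (adjusted p = 0.847), with ALDH1A3 59.4-fold, ABCC3 55.0-fold and the efflux transporter gene ABCG2 6.86-fold higher, and camera and fry gave opposite directions for this list. Counts higher and lower were 11 and 5 of 21 hypoxia and glycolysis genes (adjusted p = 0.101), 12 and 5 of 20 basal or myoepithelial genes (0.158), 11 and 7 of 24 apoptosis regulators (0.334), 2 and 5 of 10 estrogen-repressed genes (0.390), 5 and 7 of 24 cholesterol synthesis genes (0.440) and 5 and 5 of 13 mitochondrially encoded genes (0.915). The hypoxia list was called with the GC trend of each library removed (adjusted p = 0.0440). Markers of blood and endothelial cells had 1 of 5 higher, CDH5, and 1 lower (adjusted p = 0.998), with a median log2 fold change of -0.35 and a mean of 1.00. Only 2 fibroblast markers were measured, too few to test, and COL3A1 was 7.75-fold lower. ERBB2 did not pass edgeR's test, with a log2 fold change of 0.03 (95% interval -0.23 to 0.29, BH adjusted p = 0.835), and was called with the GC trend of each library removed (log2 fold change 0.18, adjusted p = 0.00667). Adjusted over the list alone, the calls came to 18 in the mesenchymal, 12 in the G1, 11 in the cholesterol and 19 in the apoptosis list, and the total was the same as over all genes in the other lists.

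In all, edgeR's quasi-likelihood test with BH adjustment called 9609 of 15256 genes between ENDX-R and vehicle, 4820 higher and 4789 lower, of which 1690 and 1922 changed at least 2-fold. Both groups were sequenced in lane 3, so lane does not enter this contrast. Genes silent in vehicle and in 4HT-R were largely absent from the deposited table, so most such genes gained in ENDX-R are missing from these counts.

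The 4HT-R line, compared with vehicle, had a smaller decrease of ESR1 than the other 2 resistant lines, lower levels of most estrogen-induced genes and higher levels of most measured NF-kappaB genes. ESR1 was 1.78-fold lower (log2 fold change -0.83, SE 0.06), PGR 18.5-fold lower at 5.43 ± 0.470 CPM, TFF1 2.03-fold lower at 369 ± 35.8 CPM and GREB1 328-fold lower. EGFR was 5.92-fold higher, IGF1R, the insulin-like growth factor 1 receptor gene, 7.23-fold lower at 113 ± 1.98 CPM and ERBB2 1.57-fold higher. FOXA1 was 1.96-fold higher, at 447 ± 4.65 against 228 ± 1.91 CPM, while GATA3 was 3.81-fold lower. CDH1, E-cadherin, was 2.22-fold lower at 750 ± 15.7 against 1667 ± 66.1 CPM. By edgeR's test with BH adjustment the adjusted p was 6.59e-09 for ESR1, 1.40e-12 for PGR, 8.85e-15 for IGF1R and 7.37e-09 for FOXA1.

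Several genes of the 4HT-R line had no counts in vehicle. OLFM4, a secreted glycoprotein of epithelia (chromosome 13, 53028741 to 53052061), was at least 4930-fold higher, CXCL8 (chromosome 4, 73740506 to 73743716) at least 2870-fold, CDC20B at least 2590-fold and SOX21 at least 1400-fold higher. KRT4, a keratin of stratified epithelia (chromosome 12, 52806543 to 52814116), was 3418-fold higher at 1021 ± 47.9 against 0.296 ± 0.0666 CPM. PCDH10, a protocadherin (chromosome 4, 133149290 to 133208606), had no counts in 4HT-R and was at least 12500-fold lower. RAMP3, which modifies the calcitonin receptor family, and PLCXD3 were at least 2020-fold and at least 367-fold lower, and MMP16, a membrane matrix metalloproteinase, and PCDH7 were 1287-fold and 646-fold lower.

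In 4HT-R against vehicle, camera with BH adjustment called 6 lists. Of 37 estrogen-induced genes, 4 rose and 29 fell (adjusted p = 1.76e-07), with GFRA1 48.1-fold and CXCL12 18.7-fold lower, and of 11 NF-kappaB genes, 9 rose and none fell (adjusted p = 0.00025), with TNFAIP3 9.74-fold, LIF 7.80-fold and RELB 4.59-fold higher. These 2 calls held with an estimated correlation (adjusted p = 0.00394 and 0.0230 with an estimated correlation). The deposited table largely lacks genes silent in both vehicle and 4HT-R. A member of the NF-kappaB list without counts in vehicle, such as CXCL8, could therefore enter mainly by its level in 4HT-R, which favours higher members. The NF-kappaB call still held among genes expressed in vehicle. Of 32 proliferation genes, 1 rose and 22 fell (adjusted p = 0.000798), CDK1 by 2.23-fold and AURKA by 1.89-fold. Of 24 cholesterol synthesis genes, 3 rose and 14 fell (adjusted p = 0.0126), IDI1 by 3.56-fold and HMGCR, the rate-limiting enzyme of the pathway, by 1.88-fold, while DHCR24 rose 1.91-fold. Of 30 luminal genes, 6 rose, TBX3 by 9.36-fold, and 16 fell (adjusted p = 0.0279), SCUBE2 by 13.5-fold. Of 23 mesenchymal genes, 13 rose and 5 fell (adjusted p = 0.0279), CCN2 by 24.0-fold, FBN1, fibrillin 1, by 10.2-fold and TGFB2 by 6.90-fold upward. The last 4 calls ended with an estimated correlation (adjusted p = 0.129, 0.0780, 0.159 and 0.129 with an estimated correlation, in that order). The mesenchymal call also ended without vehicle replicate 3 (adjusted p = 0.0566), with the leading axis of variation within groups as covariate (0.0608), without the 4 libraries at 1 end of that axis (0.0963) and with the GC trend of each library removed (0.0765). The luminal call ended among genes expressed in vehicle (adjusted p = 0.056).

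The remaining lists were not called in 4HT-R against vehicle by camera with BH adjustment. Of 33 interferon-response genes, 16 were higher and 8 lower (adjusted p = 0.0623), with IFIT3 10.6-fold higher and HERC5 12.9-fold lower, and of 13 antigen-presentation genes, 7 were higher and none lower (adjusted p = 0.0582), B2M by 1.43-fold. The antigen-presentation list was called without 4HT-R replicate 1 (adjusted p = 0.0410). Of 19 steroid receptor and coregulator genes, 3 were higher and 12 lower (adjusted p = 0.0582), with GPER1, a G protein-coupled estrogen receptor gene, 113-fold and the coactivator gene NCOA3 1.98-fold lower. In the drug metabolism and transport list of 20, 8 were higher and 6 lower (adjusted p = 0.499), with ALDH1A3 47.5-fold and ABCC3 35.5-fold higher and ABCG2 13.7-fold lower at 3.49 ± 0.285 against 47.8 ± 3.01 CPM. Counts higher and lower were 12 and 6 of 28 growth factor genes (0.113), 15 and 6 of 24 apoptosis regulators (0.116), 5 and 2 of 10 estrogen-repressed genes (0.224), 2 and 6 of 13 mitochondrially encoded genes (0.237), 3 and 1 of 5 blood and endothelial markers (0.237), 8 and 4 of 20 stress-response genes (0.307), 7 and 11 of 20 basal genes (0.307), 7 and 3 of 13 immediate early genes (0.321), 3 and 7 of 13 G1 regulators (0.358), 8 and 9 of 21 hypoxia genes (0.495) and 2 and 6 of 17 histone genes (0.499). Among these, KDR, which encodes a receptor of vascular endothelial growth factor, was 48.0-fold higher at 8.62 ± 0.753 CPM, TP63 was 12.4-fold higher, EGR1 was higher by a log2 fold change of 3.53, and TRIM29 was 29.9-fold lower. Of the 2 fibroblast markers, COL3A1 was 27.8-fold higher at 240 ± 9.6 CPM and COL1A1 2.03-fold lower, and MT-ND1 was 1.79-fold lower, beside the lower mitochondrial share of these libraries. The hypoxia list had a median log2 fold change of -0.03 and a mean of 0.39. Adjusted over the list alone, the calls came to 34 in the estrogen-induced, 23 in the luminal, 24 in the proliferation, 19 in the cholesterol, 18 in the hypoxia, 15 in the drug metabolism and 9 in the mitochondrial list, and the total was the same as over all genes in the others.

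Between 4HT-R and vehicle, edgeR with BH adjustment called 9421 genes, 4636 higher and 4785 lower, of which 2041 and 1564 changed at least 2-fold. VIM did not pass edgeR's test (log2 fold change 0.08, 95% interval -0.23 to 0.39, BH adjusted p = 0.650), nor did the proliferation marker MKI67 (-0.15, interval -0.29 to -0.01, adjusted p = 0.0533). Without 4HT-R replicate 1, MKI67 was called (log2 fold change -0.19, adjusted p = 0.0372), and so it was with the GC trend of each library removed (adjusted p = 0.0201), with the leading axis of variation within groups as covariate (0.00178) and without the 4 libraries at 1 end of it (0.0426). Vehicle was sequenced in lane 3 and 4HT-R in lane 4, so the effects of lane and line cannot be told apart in this contrast.

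The ICI-R line, compared with vehicle, had the lowest ESR1 level of the 4 lines and gained CEACAM6, FBN2, CLDN1 and interferon-response genes. These gains were not particular to ICI-R, as ENDX-R had them too. Per library, CLDN1 stood at 94.2 to 117.5 CPM in ENDX-R, and CEACAM6 at 224.2 to 253.8 in ENDX-R and 71.5 to 75.48 in 4HT-R. ESR1 was 14.5-fold lower (log2 fold change -3.86, SE 0.06), TFF1 26.2-fold lower at 28.5 ± 2.60 CPM, PDZK1, an estrogen-induced scaffold protein gene, 7.21-fold lower and CCND1, cyclin D1 (chromosome 11, 69641105 to 69654474), 1.68-fold lower at 403 ± 22.8 against 677 ± 23.8 CPM. PGR had so few counts in ICI-R that its ratio, 11200-fold lower, had a counting interval of 2010 to 442000, and GFRA1 was 60400-fold lower (16700 to 499000). EGFR was 9.95-fold, ERBB2 1.73-fold higher and IGF1R 4.16-fold lower. MKI67 was 1.31-fold lower, at 573 ± 43.4 against 750 ± 36.9 CPM. By edgeR's test with BH adjustment the adjusted p was 1.34e-15 for ESR1, 2.59e-08 for CCND1 and 0.000115 for MKI67.

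FBN2, fibrillin 2 (chromosome 5, 128257909 to 128538042), was 682-fold higher in ICI-R than in vehicle at 56.5 ± 0.856 CPM, and CLDN1, a tight junction protein gene, 544-fold higher at 71.1 ± 2.07 CPM. CDH5 and AUTS2 were 2730-fold (counting interval 489 to 108000) and 2150-fold (385 to 84800) higher, and TDRD1 1170-fold higher (401 to 5680). PCDH10 was at least 11100-fold lower, RAMP3 635-fold and ERBB4, a receptor tyrosine kinase gene, 553-fold lower, and BCL2 was 483-fold lower.

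Camera with BH adjustment called 8 lists in ICI-R against vehicle. Of 37 estrogen-induced genes, 4 rose and 33 fell (adjusted p = 9.53e-16), with EGR3 57.5-fold lower, and of 10 estrogen-repressed genes, 8 rose and 1 fell (adjusted p = 0.00482), with BCAS1 8.19-fold, BLNK 4.46-fold and BTG2 4.14-fold higher. Of 33 interferon-response genes, 24 rose and 5 fell (adjusted p = 3.49e-05), with IFIT2 42.9-fold, IFIT3 30.4-fold and SAMD9 24.4-fold higher, and all 13 antigen-presentation genes rose (adjusted p = 7.62e-06), B2M by 5.16-fold and TAP1 by 4.40-fold. Of 11 NF-kappaB genes, 7 rose and 1 fell (adjusted p = 0.00116), with ICAM1 4.74-fold and CXCL8 at least 42.9-fold higher. CXCL8 had 46, 38 and 31 counts in ICI-R, and its presence in the filtered table carries the same limit as in ENDX-R. Of 24 cholesterol synthesis genes, 3 rose, CYP51A1 by 2.54-fold, and 18 fell (adjusted p = 0.00482). These 6 calls held, with adjusted p from 0.000264 to 0.0454 with an estimated correlation. Of 30 luminal genes, 7 rose and 17 fell (adjusted p = 0.0224), TFF3 by 31.2-fold and AGR2 by 18.6-fold downward, and of 32 proliferation genes, 1 rose and 22 fell (adjusted p = 7.73e-05), MYBL2 by 1.97-fold and UBE2C by 1.67-fold. The calls of these 2 lists ended with an estimated correlation (adjusted p = 0.146 and 0.0600 with an estimated correlation).

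The other lists were not called in ICI-R against vehicle by camera with BH adjustment. Of 23 mesenchymal genes, 12 were higher and 6 lower (adjusted p = 0.0692), with SNAI2 30.7-fold higher and COL6A1 25.3-fold lower. This list was called with CPM of at least 1 in 3 libraries (0.0188), without vehicle replicate 1 (0.0379) and among genes expressed in vehicle (0.0291). VIM did not pass edgeR's test (log2 fold change 0.22, 95% interval -0.09 to 0.54, adjusted p = 0.205). Of 28 growth factor genes, 13 were higher, IGFBP3 by 27.4-fold, and 9 lower, AREG, amphiregulin, by 14.9-fold (adjusted p = 0.512). In the drug metabolism and transport list of 20, 9 were higher and 7 lower (adjusted p = 0.291), with ABCC3 29.0-fold and ABCG2 6.17-fold higher at 294 ± 9.15 CPM. Counts higher and lower were 9 and 3 of 20 stress-response genes (0.132), 11 and 4 of 24 apoptosis regulators (0.142), 3 and 9 of 13 G1 regulators (0.179), 6 and 9 of 19 steroid receptors and coregulators (0.193), 2 and 4 of 17 histone genes (0.358), 2 and 1 of 5 blood and endothelial markers (0.573), 7 and 4 of 13 immediate early genes (0.576), 8 and 6 of 21 hypoxia genes (0.610), 7 and 10 of 20 basal genes (0.752) and 4 and 5 of 13 mitochondrially encoded genes (0.752), and 1 of the 2 fibroblast markers was higher and 1 lower. Among these, HERPUD1 was 5.39-fold, CDKN2B 1.80-fold and COL17A1, a hemidesmosome collagen gene, 42.1-fold higher, and ITGA6 was 6.50-fold lower. Median and mean log2 fold changes differed in sign for the basal (-0.45 and 0.12), growth factor (0.16 and -0.05) and drug metabolism lists (0.32 and -0.18). Adjusted over the list alone, the calls came to 24 in the proliferation, 18 in the basal, 10 in the NF-kappaB and 16 in the apoptosis list, and the total was the same as over all genes in the others.

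Between ICI-R and vehicle, edgeR with BH adjustment called 8471 genes, 4249 higher and 4222 lower, of which 1627 and 1360 changed at least 2-fold. Vehicle was sequenced in lane 3 and ICI-R in lane 4, so lane and line cannot be told apart here. Genes gained in ICI-R but silent in vehicle and 4HT-R are largely missing from the deposited table.

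**Figure D2:**
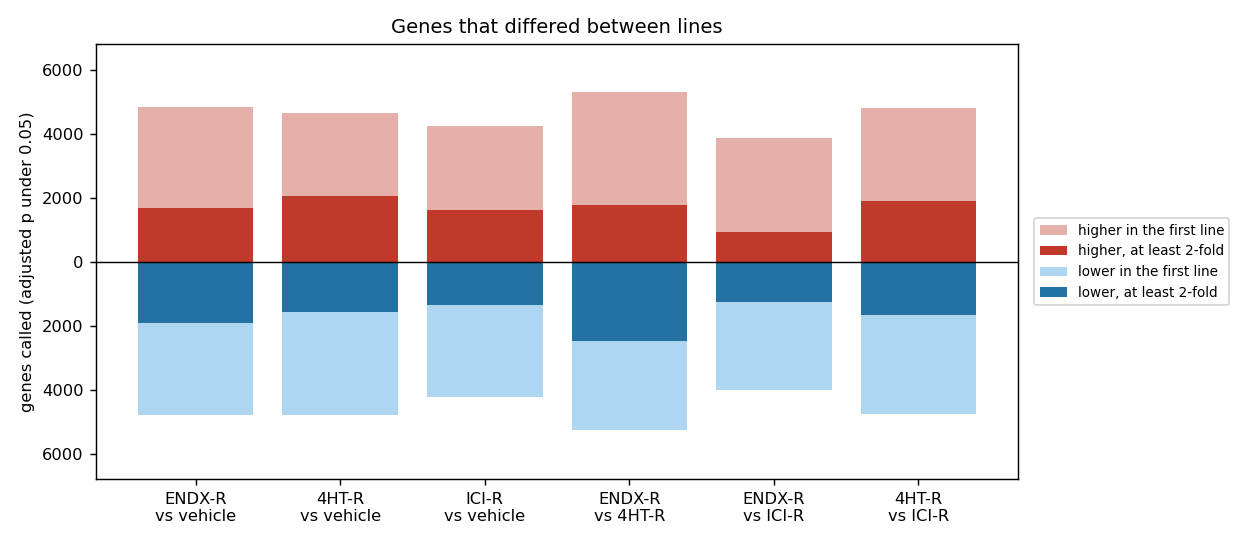
Number of genes called by edgeR (BH adjusted p under 0.05) in each of the 6 contrasts, with genes higher in the first-named line drawn above 0, lower ones below 0, and the darker part of each bar counting those that changed at least 2-fold. ENDX-R against 4HT-R has the most, 10542, and ENDX-R against ICI-R the fewest, 7860. The deposited table largely lacks genes silent in both vehicle and 4HT-R, so contrasts with ENDX-R or ICI-R are undercounted.

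Endoxifen differs from 4-hydroxytamoxifen by the loss of 1 N-methyl group, and the ENDX-R and 4HT-R lines had the same concentration (1 µM) and duration (24 months). Each antiestrogen had 1 line, so in every contrast an effect of the drug cannot be told apart from other differences between the lines. ENDX-R had 4.81-fold less ESR1 than 4HT-R (log2 fold change -2.27, SE 0.06), 136-fold less PGR, 6.4-fold less TFF1, 2.40-fold less PDZK1 and 7.93-fold less FOXA1. EGFR was 1.46-fold higher in ENDX-R, IGF1R 1.66-fold higher, ERBB2 1.54-fold lower and VIM 2.36-fold lower. By edgeR's test with BH adjustment the adjusted p was 1.30e-13 for ESR1, 2.47e-11 for PGR, 5.20e-14 for FOXA1 and 0.000401 for ERBB2. ABCG2, an efflux transporter gene (chromosome 4, 88090264 to 88231417), was 93.6-fold higher in ENDX-R (log2 fold change 6.55, SE 0.11), and CXCL8 was 108-fold lower at 0.624 ± 0.216 against 68.7 ± 9.44 CPM.

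For 3 of the fixed genes the difference between ENDX-R and 4HT-R did not pass edgeR's test with BH adjustment, and for 2 of these it did under other settings. CCND1 stood at 552 ± 9.57 and 548 ± 12.2 CPM, a log2 fold change of 0.01 with a 95% interval of -0.11 to 0.13 (adjusted p = 0.865). GATA3 stood at 303 ± 16.7 and 278 ± 25.9 CPM, a log2 fold change of 0.13 with an interval of -0.04 to 0.29 (adjusted p = 0.162), and was called with the GC trend of each library removed (log2 fold change 0.24, adjusted p = 0.000234) or with the leading axis of variation within groups as covariate (adjusted p = 0.00515). GREB1 stood at 5.43 ± 0.851 and 4.56 ± 0.676 CPM, a log2 fold change of 0.25 with an interval of 0.01 to 0.50 (adjusted p = 0.0634). GREB1 was called without ENDX-R replicate 1 (log2 fold change 0.38, adjusted p = 0.005) and without 4HT-R replicate 3 (0.37, adjusted p = 0.0118). It was also called with the GC trend removed (0.36, adjusted p = 0.00294), with the axis as covariate (0.25, adjusted p = 0.0181) and without the 4 libraries at 1 end of the axis (0.28, adjusted p = 0.0185). MKI67 was lower in ENDX-R by a small margin (log2 fold change -0.16, adjusted p = 0.0377), a call that ended without any 1 of the ENDX-R replicates or without 4HT-R replicate 1 or 2 (adjusted p = 0.0506 to 0.131), with the replicate block (0.0595) and without the 4 libraries at 1 end of the axis (0.0975).

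Among the highest fold changes between the lines, DIO2 was 5166-fold and DHRS2, a dehydrogenase/reductase gene, 1543-fold higher in ENDX-R than in 4HT-R, the latter at 1436 ± 32.7 against 0.928 ± 0.292 CPM. KLK8, a secreted serine protease gene, and S100A8, a calcium-binding protein gene, were 4270-fold (counting interval 765 to 169000) and 3960-fold (709 to 156000) higher, and PLCXD3 was at least 1110-fold higher. SULF1, an extracellular sulfatase gene (chromosome 8, 69466624 to 69660912), was 4898-fold lower in ENDX-R at 0.153 CPM against 780 ± 35.9 CPM. OLFM4 and CDKN2B were at least 4280-fold and at least 869-fold lower, and CDC20B and TMTC1 2250-fold (769 to 10900) and 1710-fold (584 to 8280) lower.

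Camera with BH adjustment called 5 lists between ENDX-R and 4HT-R. Of 37 estrogen-induced genes, 8 were higher in ENDX-R and 23 lower (adjusted p = 0.0071), with GFRA1 183-fold and ELOVL2 94.1-fold lower and CCN5 17.9-fold higher. Of 33 interferon-response genes, 27 were higher and 3 lower (adjusted p = 1.84e-07), SAMD9 by 44.0-fold, HERC5 by 40-fold and IFI6 by 13.8-fold upward. All 13 antigen-presentation genes were higher (adjusted p = 0.000152), B2M by 4.68-fold. These 3 calls held with an estimated correlation (adjusted p = 0.0477, 0.0248 and 0.0301 with an estimated correlation). Of 20 stress-response genes, 14 were higher and 2 lower (adjusted p = 0.0132), HERPUD1 by 4.97-fold and ATF3 by 5.91-fold upward, and none of 17 histone genes was higher and 16 were lower (adjusted p = 0.000152), H3C8 by 5.52-fold. The calls of these 2 lists ended with an estimated correlation (adjusted p = 0.0876 and 0.114 with an estimated correlation).

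Lists not called between ENDX-R and 4HT-R by camera with BH adjustment still held genes that passed edgeR's test in both directions. Of 20 basal genes, 12 were higher in ENDX-R, TRIM29 by 209-fold and CAV1 by 21.5-fold, and 4 lower, TP63 by 247-fold (adjusted p = 0.0632). The basal list was called without ENDX-R replicate 1 (0.0469), without 4HT-R replicate 3 (0.0479), among genes expressed in vehicle (0.0393) and with the GC trend removed (0.0210). Of 24 cholesterol synthesis genes, 13 were higher and 2 lower (adjusted p = 0.0755), IDI1 by 2.79-fold upward. The cholesterol list was called without ENDX-R replicate 1 (0.0497), without the 4 libraries at 1 end of the leading axis of variation within groups (0.0453) and with the GC trend removed (0.0111). Of 23 mesenchymal genes, 9 were higher, SERPINE1 by 689-fold and LOXL2 by 104-fold, and 10 lower, FBN1 by 26.1-fold (adjusted p = 0.920), with a median log2 fold change of -0.20 and a mean of 0.58. Of 20 drug metabolism genes, 8 were higher and 10 lower (adjusted p = 0.473), and of 11 NF-kappaB genes, 4 and 7 (adjusted p = 0.283). Counts higher and lower were 3 and 7 of 10 estrogen-repressed genes (0.208), 2 and 5 of 13 G1 regulators (0.240), 10 and 14 of 30 luminal genes (0.260), 7 and 3 of 13 immediate early genes (0.260), 18 and 10 of 32 proliferation genes (0.323), 8 and 4 of 13 mitochondrially encoded genes (0.378), 11 and 8 of 21 hypoxia genes (0.473), 6 and 9 of 19 steroid receptors and coregulators (0.473), 8 and 14 of 28 growth factor genes (0.518), 1 and 3 of 5 blood and endothelial markers (0.518) and 11 and 9 of 24 apoptosis regulators (0.992), and 1 of the 2 fibroblast markers was higher and the other, COL3A1, 216-fold lower. AGR2, a protein disulfide isomerase gene of the luminal list, was 91.9-fold lower, AR 49.5-fold lower and KDR 61.0-fold lower in ENDX-R, and MET was 10.1-fold and NR3C2 19.6-fold higher. Adjusted over the list alone, the calls came to 23 in the growth factor and 19 in the drug metabolism list, and the total was the same as over all genes in the others.

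Between ENDX-R and 4HT-R, edgeR with BH adjustment called 10542 genes, 5299 higher and 5243 lower in ENDX-R, of which 1765 and 2473 changed at least 2-fold. Genes gained in ENDX-R but silent in vehicle and 4HT-R are largely missing from the deposited table. The numbers higher in ENDX-R are therefore undercounted and cannot be set against the numbers lower. ENDX-R was sequenced in lane 3 and 4HT-R in lane 4, so lane and line cannot be told apart, and fold changes between these lines followed the GC content of genes (Spearman correlation -0.356 across 10400 genes, which are not independent replicates). The same correlation was 0.297 for 4HT-R against ICI-R and -0.217 for ENDX-R against vehicle, both within 1 lane, and 0.2, -0.123 and -0.142 for 4HT-R against vehicle, ICI-R against vehicle and ENDX-R against ICI-R, which cross lanes.

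**Figure D3:**
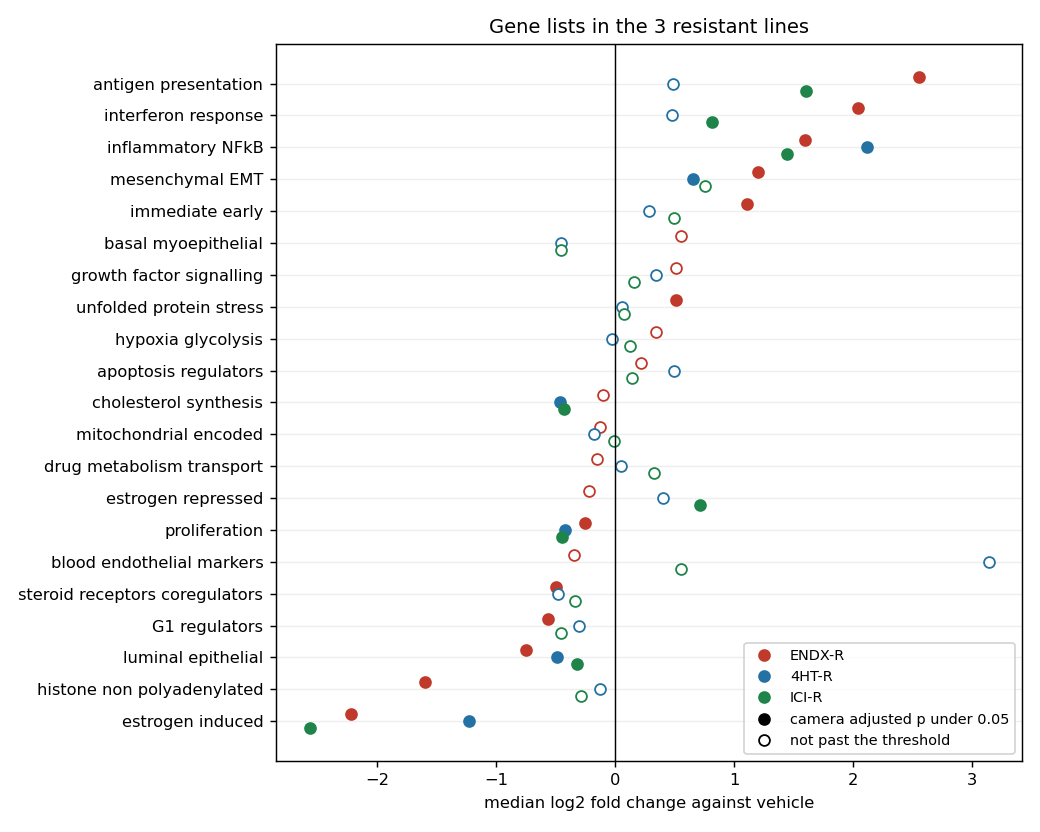
Median log2 fold change against vehicle of each of the 21 tested gene lists in ENDX-R, 4HT-R and ICI-R, with filled points where camera called the list (BH adjusted p under 0.05) and open points where it did not, so that estrogen-induced genes are filled and below 0 in all 3 lines. Medians use fitted values, and with genes at 0 counts set to their bound the NF-kappaB medians of 1.59 in ENDX-R and 1.44 in ICI-R become 1.10 and 1.24.

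ENDX-R and ICI-R were compared directly as the endoxifen line against the line kept in a receptor antagonist of another class. ENDX-R had more ESR1 (log2 fold change 0.76, SE 0.06), TFF1 (1.02) and CCND1 (0.45) than ICI-R, and less FOXA1 (-1.20), GATA3 (-0.64), VIM (-1.38) and AR (-4.42). SERPINE1 (7.70), DIO2 (4.13) and AREG (4.64) were higher in ENDX-R, and STAT6, a transcription factor of interleukin 4 signalling (-6.05), and SNTB1 (-4.74) were lower, while SLFN11 and CDKN2B were at least 1560-fold and at least 601-fold lower. GREB1, IGF1R, ABCG2 and MKI67 did not pass edgeR's test with BH adjustment, with log2 fold changes of -0.12, -0.07, 0.15 and 0.08 and adjusted p of 0.410, 0.310, 0.124 and 0.328.

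By camera with BH adjustment, ENDX-R and ICI-R differed in 9 lists. Of 33 interferon-response genes, 27 were higher in ENDX-R and none lower (adjusted p = 1.08e-07), SAMD9 by a log2 fold change of 2.81 and IFIT3 by 2.08, and this call held (adjusted p = 0.0225 with an estimated correlation). Histone genes were lower in 15 of 17 (adjusted p = 6.73e-06), luminal genes in 21 of 30 with 5 higher (0.000221), estrogen-repressed genes in 8 of 10 with 1 higher (0.00228) and G1 regulators in 6 of 13 with 2 higher (0.0345). Stress-response genes were higher in 9 of 20 with 3 lower (adjusted p = 0.0195), immediate early genes in 7 of 13 with none lower (0.0195), hypoxia and glycolysis genes in 11 of 21 with 1 lower (0.0148) and cholesterol synthesis genes in 12 of 24 with 3 lower (0.0410). LDHA (log2 fold change 1.91), FOSL1 (2.64) and FOS (2.21) were among the higher genes and RBL2 (-0.98) and IL1R1 (-4.13) among the lower. These 8 calls ended with an estimated correlation (adjusted p from 0.0635 to 0.248 with an estimated correlation). The cholesterol call also ended without ENDX-R replicate 3 (adjusted p = 0.0603), without ICI-R replicate 3 (0.074) and without the 4 libraries at 1 end of the leading axis of variation within groups (0.0557). That axis as covariate ended the G1 and immediate early calls (both 0.0666), removal of the GC trend the G1 call (0.066) and leaving out the 4 libraries the immediate early call (0.0504). The estrogen-induced list had 18 higher and 12 lower (adjusted p = 0.429) and antigen presentation 6 higher and 1 lower of 13 (adjusted p = 0.107). Adjusted over the list alone, the calls came to 32 in the estrogen-induced, 27 in the luminal and 8 in the immediate early list.

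Between ENDX-R and ICI-R, edgeR with BH adjustment called 7860 genes, 3861 higher and 3999 lower in ENDX-R, of which 931 and 1272 changed at least 2-fold. ENDX-R was sequenced in lane 3 and ICI-R in lane 4, so lane and line cannot be told apart, and genes gained in either line but silent in vehicle and 4HT-R are largely missing.

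4HT-R and ICI-R shared lane 4, and their direct contrast showed higher levels of ESR1 and of most estrogen-induced genes in 4HT-R. ESR1 was higher by a log2 fold change of 3.02 (SE 0.06), TFF1 by 3.69, PDZK1 by 1.62, FOXA1 by 1.79, AGR2 by 4.08 and CA12, an estrogen-induced carbonic anhydrase gene, by 4.03, and PGR was 607-fold higher (counting interval 109 to 24000) and GFRA1 1260-fold higher (348 to 10400). CXCL8 (6.06), COL3A1 (7.05), KDR (5.03) and ERBB4 (8.16) were higher in 4HT-R, and ABCG2 (-6.4), CLDN1 (-6.28), HERC5 (-4.09), B2M (-1.85) and EGFR (-0.75) were lower. GREB1 did not follow the other estrogen-induced genes named, at 3.96 to 5.29 CPM per library in 4HT-R against 5.70 to 6.04 in ICI-R. IGF1R stood at 110.6 to 114.6 CPM in 4HT-R against 190.9 to 201.6 in ICI-R. ERBB2 and VIM did not pass edgeR's test with BH adjustment, with log2 fold changes of -0.14 and -0.14 and adjusted p of 0.336 and 0.403.

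By camera with BH adjustment, 23 of 37 estrogen-induced genes were higher in 4HT-R than in ICI-R and 7 lower (adjusted p = 0.000308), and none of 13 antigen-presentation genes was higher and all 13 were lower (adjusted p = 0.000591). These calls held with an estimated correlation (adjusted p = 0.0253 and 0.0407 with an estimated correlation). Of 33 interferon-response genes, 6 were higher and 21 lower (adjusted p = 0.0154), a call that ended with an estimated correlation (adjusted p = 0.163 with an estimated correlation) and among genes expressed in vehicle (adjusted p = 0.16). The other 18 lists tested were not called, though the basal list was among genes expressed in vehicle (0.0376), with the leading axis of variation within groups as covariate (0.0414) and with the GC trend removed (0.0251). Adjusted over the list alone, 31 estrogen-induced genes passed. In all, edgeR with BH adjustment called 9575 genes, 4816 higher and 4759 lower in 4HT-R, of which 1896 and 1661 changed at least 2-fold. Genes gained in ICI-R but silent in vehicle and 4HT-R are largely missing, so the numbers lower in 4HT-R are undercounted.

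Line-specific genes were those that edgeR with BH adjustment called in the same direction against vehicle and against each of the other 2 resistant lines. The 4HT-R line had 4515, with 2283 higher and 2232 lower, the ENDX-R line 3595, with 1833 and 1762, and the ICI-R line 1896, with 1071 and 825. In ENDX-R, CDH5, DIO2, ROR1, TDRD1 and TCIM led the higher genes, and SLFN11, CDKN2B, CA2, STAT6 (740-fold lower at 0.188 ± 0.137 against 145 ± 8.86 CPM in vehicle) and SCIN (470-fold lower), an actin-severing protein gene, the lower ones. A gene named here differed by the test and can have changed nearly as much in other lines. CDH5 stood at 28.5 ± 3.33 CPM in ENDX-R and 21.8 ± 1.26 in ICI-R. TDRD1 stood at 39.4 ± 5.50 CPM in ENDX-R, 27.3 ± 2.99 in 4HT-R and 28.2 ± 3.29 in ICI-R. In 4HT-R the higher genes were led by OLFM4, CXCL8, CDC20B, SOX21 and KRT4, and the lower ones by RAMP3, PLCXD3, MMP16, PCDH7 and HMCN1 (493-fold lower). RAMP3 was nearly lost in the other resistant lines too, at 0.0711 ± 0.0776 CPM in ENDX-R and 0.0736 ± 0.0603 in ICI-R against 47.5 ± 6.85 in vehicle. CA2, named for ENDX-R at 0.260 ± 0.0767 CPM, stood at 3.33 ± 0.289 in 4HT-R and 0.885 ± 0.227 in ICI-R against 355 ± 6.80 in vehicle. In ICI-R, FBN2 (56.5 ± 0.856 CPM, against 44.8 ± 3.46 in ENDX-R), CEACAM6, a cell adhesion glycoprotein gene (374-fold higher at 784 ± 36.2 against 2.08 ± 0.477 CPM), PPP2R2B (355-fold), SNTB1 (312-fold) and GABBR2 (198-fold) led the higher genes, and GFRA1, ERBB4, RUBCNL (76.2-fold, counting interval 25.8 to 372), CA12 (44.7-fold) and SYTL5 (28.2-fold) the lower ones, and GFRA1 stood at 0.123 ± 0.0994 CPM in ENDX-R too. With a change of at least 2-fold required in every contrast used, the numbers were 1452, 841 and 360. The 4HT-R and ICI-R lines share lane 4, and genes specific to ENDX-R had to differ within lane 3 and across lanes. The deposited table largely lacks genes silent in both vehicle and 4HT-R. Higher genes specific to ENDX-R or ICI-R are therefore undercounted, and the numbers of higher genes cannot rank the lines.

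All 3 resistant lines shared 3364 genes called by edgeR in the same direction against vehicle, 1685 higher and 1679 lower, and 1146 with a change of at least 2-fold in each. EGFR, ALDH1A3, ABCC3, DDIT4 and TNFAIP3 were higher and ESR1, PGR, GREB1, BCL2, IGF1R and SCUBE2 lower in each line. Independent lists of the same sizes would share 408 higher and 416 lower genes, and simulated lines without any change shared 0, which follows from 0 genes being called in them. Ranked by p in place of calls, with as many genes taken per line as edgeR called in the real lines, simulated unchanged lines shared 3160 in the same direction, a value computed after the results were seen. Those simulated genes passed no test, unlike the real calls, so the 3160 cannot say how many of the 3364 the common vehicle libraries bring. The number of shared genes alone is therefore not read as a shared effect, and the 3 vehicle libraries cannot be divided into parts of at least 2.

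ENDX-R and ICI-R had the closest profiles of the 3 pairs of resistant lines. Their log2 differences from vehicle correlated across genes with a Pearson r of 0.776 (Spearman 0.651), against 0.466 (0.337) for ENDX-R and 4HT-R and 0.539 (0.416) for 4HT-R and ICI-R, and genes are not independent replicates. Simulated unchanged lines sharing the vehicle libraries gave r of 0.486, 0.491 and 0.495 in that order of pairs. The covariance was 1.265, 0.866 and 0.892, against simulated values of 0.0206, 0.0205 and 0.0207, which left 1.244, 0.846 and 0.871. The simulated values cover noise between libraries only. A change particular to the 1 vehicle line enters the differences of all 3 resistant lines and stays in what is left. What is left is therefore not read as a shared effect. Of genes called against vehicle in both lines, 89.2% went the same way in ENDX-R and ICI-R (2905 higher and 2803 lower, where independent lists give 1342 and 1325), 71.5% in ENDX-R and 4HT-R (2270 and 2317, expected 1465 and 1502) and 77.8% in 4HT-R and ICI-R (2320 and 2293, expected 1291 and 1324). Among as many genes of lowest p in simulated unchanged lines, which share the vehicle libraries, 81.6%, 80.4% and 82.2% went the same way in that order of pairs. The share lay above its simulated value for ENDX-R and ICI-R and below it for the other 2 pairs. The simulated lines leave out the real effects of each line, and their genes passed no test. Without use of the vehicle libraries, the mean squared log2 difference between lines, less the part due to spread between libraries, was 0.698 for ENDX-R and ICI-R, 1.943 for ENDX-R and 4HT-R and 1.508 for 4HT-R and ICI-R. The same measure from vehicle was 1.779 for ENDX-R, 1.846 for 4HT-R and 1.402 for ICI-R. By these values ENDX-R and ICI-R each lay nearer to vehicle than to 4HT-R. The difference between the distances of ENDX-R from 4HT-R and from ICI-R was 1.244 (jackknife SE 0.0714, range without each library 1.208 to 1.307), so ENDX-R lay closer to ICI-R by more than the spread between libraries.

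**Figure D4:**
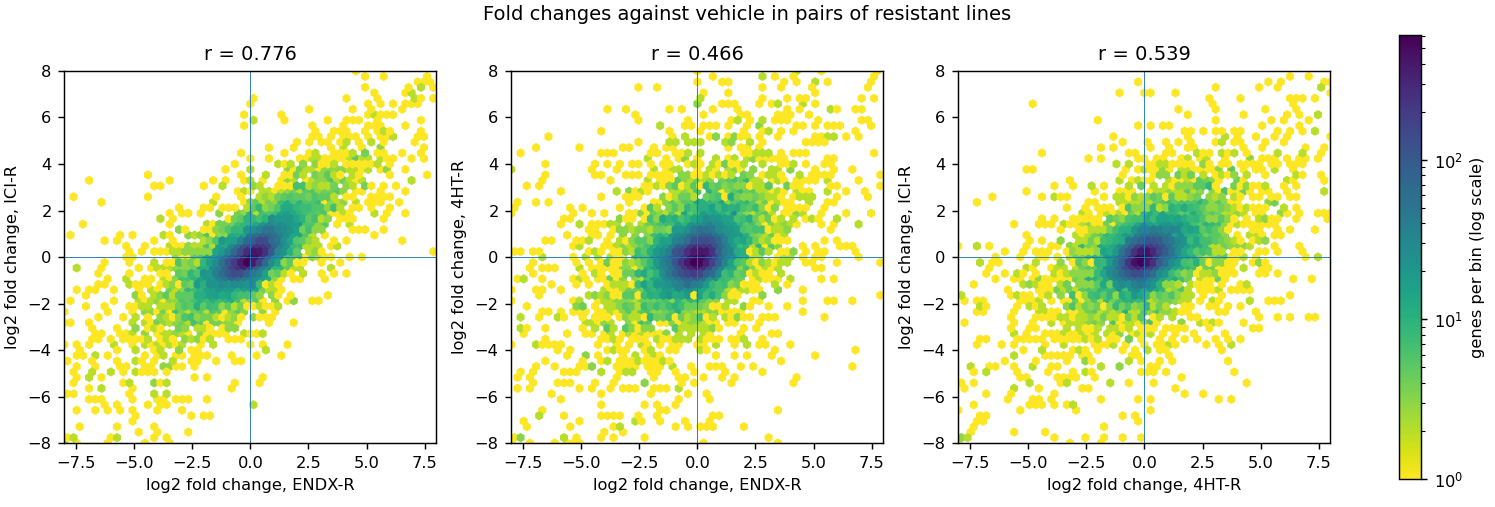
Log2 fold changes against vehicle from edgeR in pairs of resistant lines, as hexagonal bins coloured by the number of genes (log scale), with axes drawn to 8 in either direction and 111, 162 and 145 genes beyond them for ENDX-R and ICI-R, ENDX-R and 4HT-R, and 4HT-R and ICI-R. The r above each panel (0.776, 0.466 and 0.539 in that order) comes from differences of mean log2 CPM, and the bins follow the diagonal most closely for ENDX-R and ICI-R.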

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

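The contrasts in this part were all planned. Each gene below is one that the naming rule had picked and that edgeR with BH adjustment called in opposite directions against vehicle in different resistant lines, with a called difference between those lines. Lane and line cannot be told apart in contrasts of ENDX-R with 4HT-R or ICI-R, while 4HT-R and ICI-R shared a lane.

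FOXA1, a transcription factor that opens chromatin for the estrogen receptor, stood at 228 CPM in vehicle, 56.4 in ENDX-R, 447 in 4HT-R and 129 in ICI-R, and its log2 fold change was -2.99 between ENDX-R and 4HT-R and 1.79 between 4HT-R and ICI-R. DIO2 stood at 0.533, 1245, 0.239 and 71.0 CPM in the same order of lines, with log2 fold changes of 12.33 for ENDX-R against 4HT-R and -8.20 for 4HT-R against ICI-R. The lower DIO2 level in 4HT-R than in vehicle rests on few counts, 10, 3 and 17 against 16, 25 and 24. Its log2 fold change there was -1.12 (SE 0.39, edgeR, BH adjusted p = 0.0218), and the CPM of the 2 groups overlapped. CDKN2B stood at 9.21, 0, 24.0 and 16.6 CPM and was at least 869-fold lower in ENDX-R than in 4HT-R and at least 601-fold lower than in ICI-R.

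PLCXD3 stood at 8.81 CPM in vehicle, 26.4 in ENDX-R, 0 in 4HT-R and 0.6 in ICI-R. It was at least 1110-fold higher in ENDX-R than in 4HT-R, and higher than in ICI-R by a log2 fold change of 5.45. KLK8 stood at 3.02, 33.7, 0.00806 and 0.964 CPM and was 4270-fold higher in ENDX-R than in 4HT-R (95% counting interval 765 to 169000) and higher than in ICI-R by a log2 fold change of 5.13. S100A8 stood at 0.308, 31.3, 0.00791 and 31.8 CPM, 3960-fold higher in ENDX-R than in 4HT-R (95% counting interval 709 to 156000) and 4010-fold lower in 4HT-R than in ICI-R (720 to 159000).

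DHRS2 stood at 14.1 CPM in vehicle, 1436 in ENDX-R, 0.928 in 4HT-R and 92.0 in ICI-R, with log2 fold changes of 10.59 for ENDX-R against 4HT-R and -6.63 for 4HT-R against ICI-R. SULF1 showed the opposite order, at 33.8, 0.153, 780 and 0.761 CPM, with log2 fold changes of -12.26 and 10.01. TMTC1 stood at 2.86, 0.0290, 47.1 and 1.20 CPM, 1710-fold lower in ENDX-R than in 4HT-R (counting interval 584 to 8280) and higher in 4HT-R than in ICI-R by a log2 fold change of 5.28.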

How the results depend on the processing

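The tests with only genes expressed in vehicle, with the axis within groups as covariate, without the 4 libraries at 1 end of that axis and with the GC trend removed were chosen only after the results were seen. Over all alternatives, 225 of the counts of called, line-specific and shared genes and the distance between lines stayed within their limits and 6 moved. Requiring a 2-fold change in every contrast used left 841 genes specific to ENDX-R, 1452 to 4HT-R, 360 to ICI-R and 1146 shared by the 3 lines, as the requirement itself removes smaller changes. The distance of ENDX-R from 4HT-R less that from ICI-R moved from 1.244 to 0.9163 among genes with an average log2 CPM of at least 3 and to 0.8569 among genes expressed in vehicle, and the cause was not tested. Correlations of fold changes between lines stayed within their limits in 44 cases and moved in 10, 3 of them with Spearman in place of Pearson. Among genes with an average log2 CPM of at least 3, r was 0.790 for ENDX-R and ICI-R. It was 0.429 for ENDX-R and 4HT-R and 0.508 for 4HT-R and ICI-R there.

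Numbers of called lists moved under other tests of the lists in 9 cases. With fry, which tests whether a list's genes move on balance and does not compare it with other genes, 20, 20, 18, 19, 17 and 16 lists were called in ENDX-R, 4HT-R and ICI-R against vehicle, ENDX-R against 4HT-R, ENDX-R against ICI-R and 4HT-R against ICI-R. With an estimated correlation, 2 were called in 4HT-R against vehicle, 3 in ENDX-R against 4HT-R and 1 in ENDX-R against ICI-R. Over the 126 list tests, called or not, camera's alternatives kept a call in 914 cases, ended it in 32 (19 of them with an estimated correlation) and gave one to an uncalled list in 15. Fry ended none and gave 67, of which 9 went in the direction opposite to camera's.

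Lists that changed direction had not been called by camera. The lists given here are those reported singly above, so not every change of direction under fry is named. With fry the BH adjusted p was 9.95e-07 for drug metabolism in ENDX-R and 4.25e-06 for basal genes in ICI-R against vehicle. Between ENDX-R and 4HT-R it was 5.9e-06 for mesenchymal, 0.0346 for growth factor, 0.00262 for apoptosis and 0.858 for blood and endothelial genes, and between ENDX-R and ICI-R 0.983 for estrogen-induced genes. With camera, blood and endothelial markers in ENDX-R against vehicle had an adjusted p of 0.982 with CPM of at least 1 in 3 libraries, 0.954 with the replicate block, 0.944 with the axis as covariate and 0.799 to 0.996 without a library. Apoptosis regulators between ENDX-R and 4HT-R had 0.993 with RLE and 0.994 with upper quartile factors, 0.932 with CPM of at least 1 in 3 libraries, 0.992 with the block, 0.825 among genes expressed in vehicle, 0.954 with the axis, 0.933 without the 4 libraries, 0.648 without the GC trend and 0.897 to 0.999 without a library. Mesenchymal genes between these lines had 0.918 without the GC trend. Mitochondrially encoded genes had 0.541 to 0.994 in ENDX-R and 0.554 to 0.947 in ICI-R against vehicle without a library.

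Named genes kept direction and call in 6451 cases, gained a call in 12, lost it in 18 and changed sign in 13, all in genes not called. ERBB2 in ENDX-R against vehicle was -0.033 without vehicle replicate 3 and -0.0807 without ENDX-R replicate 3 (highest 0.153 without a library). VIM in 4HT-R against vehicle was -0.0265 without vehicle replicate 3, -0.00495 without 4HT-R replicate 2 (highest 0.17 without a library) and -0.0359 without the 4 libraries. CCND1 in ENDX-R against 4HT-R was -0.0138 with RLE factors and with DESeq2, -4.64e-05 with CPM of at least 1 in 3 libraries, -0.00496 in a fit of the 2 groups, -0.00744 among genes expressed in vehicle, -0.0177 without the 4 libraries, and -0.00195 and -0.00401 without ENDX-R or 4HT-R replicate 1 (highest 0.0284 without a library). The cause of these sign changes was not tested.

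With the replicate number as a block, 9115, 8932 and 7943 genes were called in ENDX-R, 4HT-R and ICI-R against vehicle, no count moved by over 1.5 times and none of the 126 list tests changed its call. The calls of 2 named genes ended under the block, in contrasts whose same-numbered libraries did not all correlate above 0.1: BAD in 4HT-R against vehicle (adjusted p = 0.0522 with edgeR) and MKI67 in ENDX-R against 4HT-R (0.0595). Correlations of deviations ran from -0.745 to 0.704 (median -0.0205) for 18 pairs with the same number and from -0.73 to 0.788 (median 0.153) for the others, and 3 of 12 libraries correlated best with their own number. BAD is named here after its values were seen. Depth limits the genes near 0 counts, for which folds are bounds or have wide intervals at up to 3 counts over a group. Folds on slightly more counts carry no interval but are imprecise too. Examples are PGR in ENDX-R (2, 0 and 2 counts) and MMP16 in 4HT-R (0, 4 and 0). In ICI-R, BCL2 (1, 0 and 3) and ERBB4 (2, 0 and 4) are further examples.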

Other observations

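The tests of flow cell lane and of cells in S phase were chosen only after the results were seen, as were the comparison with genes expressed in vehicle and the removal of the GC trend.

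Genes of some chromosome regions moved together in each line. In windows of 40 neighbouring genes (933 windows over 10084 genes), 112 in ENDX-R, 52 in 4HT-R and 89 in ICI-R against vehicle, 253 in all, had a median log2 fold change beyond the family-wise limit from 1000 shuffles of gene order. In ICI-R, overlapping windows on chromosome 7 joined into a run of 180 genes (100834036 to 156893208) with a median of -1.01 and a run of 279 genes (8113184 to 102562633) with a median of 0.62, and 130 genes of chromosome 1 (212432887 to 248919146) lay at 0.57. In ENDX-R, 251 genes of chromosome 1 (28505943 to 85276904) lay at 0.65 and 160 genes of chromosome 16 (46979 to 15888649) at -0.77. In 4HT-R, 120 genes of chromosome 3 (158644497 to 198043720) lay at 0.73 and 110 genes of chromosome 10 (134465 to 45594906) at -0.84. With the GC trend of each library removed, 212 of the 253 windows (83.8%) stayed beyond the limit in the same direction, more than GC content as the whole cause would leave. As a hypothesis, regional copy number differences between the lines may lie behind these runs, but the 253 windows are the pattern itself and no DNA was measured here, so this stays open.

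ENDX-R lay closer to ICI-R than to 4HT-R, by a difference of mean squared log2 differences of 1.244. The filter of the deposited table is argued against, because among 12812 genes expressed in vehicle the difference was still 0.857 (jackknife SE 0.0659). Flow cell lane as the cause of closeness is argued against too, because 4HT-R and ICI-R, which shared a lane, lay farther apart than ENDX-R and ICI-R, which did not, by 0.81 (SE 0.061). How much lane adds to any contrast across lanes stays open, since the lane split of the 4 groups held 28.4% of the variance between them, about as much as vehicle and ICI-R set against ENDX-R and 4HT-R (27.1%), and vehicle and 4HT-R set against ENDX-R and ICI-R held 44.6%. A shared response of the lines to antiestrogens is a biological explanation that stays untested here.

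Within groups, libraries differed along 1 shared axis that held 64.9% of the variance within groups, with vehicle replicate 3, ENDX-R replicate 1, 4HT-R replicate 1 and ICI-R replicate 3 at 1 end. Gene loadings on it followed GC content (Spearman correlation -0.855 across 10440 of 10450 genes, 99.91%, and 0.180 for length), which is consistent with a bias of library preparation or sequencing by GC content. Sequencing depth is not decided, with a Pearson r of -0.49 over the 12 libraries (exact permutation within groups, 2-sided p = 0.195, BH adjusted 0.195, Spearman rho -0.378, p = 0.340, adjusted 0.340), which fell to -0.153 without the 2 libraries farthest from the median. The mitochondrial share, the other of the 2 relations computed, followed the axis (r = 0.774, exact permutation p = 0.01, BH adjusted 0.0201, rho 0.769, p = 0.0154, adjusted 0.0309, and r = 0.714 without 2 libraries). No biological explanation was tested, since the design names none within a group.

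Histone genes on chromosome 6 (26031589 to 27810536) were lower in ENDX-R than in vehicle, with a median log2 fold change of -1.59 over 17 genes (bootstrap spread 0.158), and 13 histone genes elsewhere had a median of -2.19. In 4HT-R and ICI-R the medians were -0.13 and -0.29 on chromosome 6 (6 and 4 of 17 called lower by edgeR, 2 higher in each) and -0.59 and -0.91 elsewhere (7 and 8 of 13 lower, 0 higher). Loss of the region is argued against, since 16 other genes lying between them had a median of 0.484 (spread 0.279). Lower capture of RNA without poly(A) tails was examined in 11 other such RNAs, with a median of 0.00376 (spread 0.415). They ran from -0.736 to 1.24, with 2 called lower by edgeR and 3 higher. None fell as far as the histone median of -1.59, which argues against a loss of that size in these 11. The spread is too wide to exclude a smaller loss, and the selection of RNA is unknown, so lower capture stays open. Fewer cells in S phase were predicted to lower S phase genes by as much as the histone genes. The 15 S phase genes had a median of -0.101, above the histone median by 1.49 (spread 0.239), with 7 called lower by edgeR and 3 higher. A fall as large was therefore not seen in these genes. Whether histone transcripts fall by more than these genes when fewer cells are in S phase was not tested, so fewer cells in S phase stay open. Reads shared between near-identical histone copies were not tested and stay open, so whether the change is biological is not settled.

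Other divisions of the libraries were tried for each count. For 6 libraries of a contrast there are 10 splits, too few for a share under 0.05: with the compared groups alone, the labelled split called 9118, 9141, 8651, 9970, 7707 and 9602 genes by edgeR in ENDX-R, 4HT-R and ICI-R against vehicle, ENDX-R against 4HT-R, ENDX-R against ICI-R and 4HT-R against ICI-R, 1 of 10 splits in each, and the highest other split called 0. In 100 divisions of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many genes specific to ENDX-R (3595, highest other 0), 1 as many specific to 4HT-R (4515, highest other 302) and 1 as many shared genes (3364, highest other 0), so a chance division of the libraries can be excluded for these. These divisions do not measure how many shared genes the common vehicle libraries bring. With 1 line per antiestrogen, the divisions show that libraries group by line and not whether the antiestrogen is the source of a difference. For ICI-R 2 of 100 gave as many (1896, highest other 2167), the other being a draw in which the ICI-R label held the 3 4HT-R libraries, and a chance division of the libraries can be excluded there too. For called lists over the 6 contrasts, 6 of 100 gave at least the real 43 (highest other 54), so chance cannot be excluded for that number.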
